A study of Mus musculus with 121 samples.

How the data were processed

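RNA of 6 mouse tumours grown as transplants in the hind leg of C3H/HeMs mice was measured on CodeLink 1-colour arrays. Per the labels, RNA was extracted with ISOGEN and RNeasy and labelled with Cy5. Gamma rays (0, 30, 50 or 70 Gy) were followed by sampling from day 1 to day 41 and carbon ions (30 Gy) by sampling from hour 6 to day 42. All 121 arrays were used, 81 of the gamma and 40 of the carbon experiment, in 54 groups of tumour, beam, dose and time, of which 41 held 2 arrays and 13 held 3. The labels do not say whether the arrays of a group are separate animals. Within groups the median SD of a gene was 0.0683 log2 among gamma arrays of day 1, 0.0734 among carbon arrays and 0.112 among later gamma arrays. If pairs of arrays hold RNA of 1 tumour, p values measure the spread between arrays, which is then technical.

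The values are intensity as deposited by the authors, on a linear scale with the median of each array near 1. Normalization software, background method and spot filter are not given in the sources used. Gamma arrays lacked 9.99 to 18.62% of probes and carbon arrays 0.541 to 4.922%, and among the 10% of probes dimmest on carbon arrays 85.5% of gamma values were missing. Carbon arrays had 1831 values at or below 0. Values under a floor of 0.1269, the 5th percentile of positive values, were set to it, log2 was taken and missing values stayed missing.

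Of 36227 probes, 21615 carried 1 gene symbol, 681 several and 13931 none. Symbols came from the deposited platform annotation, and 21487 of the single-symbol probes had their Entrez identifier in the RefSeq gene table. Probes needed a value on at least 90% of arrays (28836 probes) and a mean above the 20th percentile, with 1 probe per gene, which left 12962 genes (fewer where a group lacked values). Among them 8689 had a value on every array.

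limma 3.58.1 in R 4.3.3 fitted 1 linear model of group means over all arrays (67 residual degrees of freedom), with moderated variances and a mean-variance trend. Each of 25 comparisons was a contrast of group means, tested 2-sided and adjusted by Benjamini and Hochberg, with a gene called at an adjusted p under 0.05. For a mean over tumours each tumour had equal weight, and irradiated tumours were set against unirradiated arrays of the same tumour and experiment (day 9 for late mmca). 30 gene lists were tested with camera at a preset correlation of 0.01, adjusted within a comparison, giving 262 of 750 list tests called. With an estimated correlation 33 of these stayed called, and both values are printed beside each list.

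The comparisons, gene lists, filters, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls among called genes with 1 sign in every part of a comparison, up to 4 leading members of each called list, and the p53 targets Cdkn1a, Mdm2, Ccng1 and Trp53inp1 with Mki67. Mki67 was not tested, since its probes did not pass the filter. The text names 198 of these genes (394 with their comparison), passing over those without a well-known function and, in single tumours, some of the p53 targets.

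The alternatives were quantile normalization, no filter on dim probes, every probe, a floor at the 10th percentile, no trend, array weights, only a comparison's own arrays, replicate number as a block, pooled mmca controls and leaving out each array. 4 alternatives were added after seeing the data: 1 value per group, missing values at the floor with quantile normalization, doses matched for array brightness, and the day 1 control for late mmca. Pairing was tested by correlating differences between replicates across groups. In carbon mca4 all 15 pairs of groups had r over 0.1, in carbon mmca 80% (medians 0.223 and 0.288), and elsewhere medians lay between -0.229 and 0.228.

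The method was tested on simulated data of the same design with 40 genes per change. Of genes raised by 0.5 log2, 87.5% were called in the gamma day 1 mean, 95% for gamma days 8 to 25, 72.5% at carbon day 1 and 15% for mmca against mca4 over carbon days 1 to 5 (92.5% of genes raised by 1). Unchanged genes made up 2.54, 5.31, 6.32 and 4.07% of the calls. How p values behave if arrays repeat 1 tumour was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.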

Results

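The labels name 6 transplanted mouse tumours: a radiation-induced fibrosarcoma, the spontaneous fibrosarcoma nfsa, the mammary carcinomas mmca and mca4, and the squamous cell carcinomas scc7 and nrs1. Changes are log2 differences of array intensity (a change of 1 is a 2-fold change) with the standard error (SE) of the limma model. Adjusted p values come from that model, and a gene is called risen or fallen at an adjusted p under 0.05. Below, the floor setting means missing values set to the floor before quantile normalization, and a lost call an adjusted p no longer under 0.05.

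At day 1 after gamma rays, targets of the transcription factor p53 were higher in the mean of 4 tumours (24 irradiated and 8 unirradiated arrays). Cdkn1a, a cell cycle inhibitor, rose by 2.0 ± 0.079 (SE, 1.16 to 2.91 across tumours, adjusted p = 6.07e-34). Ccng1, a cyclin G gene, rose by 1.54 ± 0.07, the death receptor gene Fas by 1.47 ± 0.075 and Ephx1, an epoxide hydrolase gene, by 1.42 ± 0.077. Mdm2, which encodes the ligase that degrades p53, rose by 0.93 ± 0.073, with values of 0.019 to 1.56 across tumours. Trp53inp1, another p53 target, gave -0.005 (adjusted p = 0.939) and 0.0877 after quantile normalization. In the p53 target list, 21 of 32 rose, 3 fell and 8 did not pass, or 21 and 3 adjusted over the list alone. The median was 0.37 (camera adjusted p = 1.1e-08, adjusted p = 0.0026 with an estimated correlation).

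Genes induced by interferons also rose on average, with wide differences between tumours. Rsad2, which encodes the antiviral protein viperin, rose by 1.61 ± 0.18 (0.24 to 3.29 across tumours), Ifit1 by 1.38 ± 0.12 (-0.07 to 3.52) and the antiviral GTPase gene Mx1 by 1.35 ± 0.11. Cxcl10, a chemokine that attracts T cells, rose by 1.26 ± 0.13 (-0.64 to 3.20). Among interferon-stimulated genes, 33 of 36 rose, 0 fell and 3 did not pass, or 34 and 0 adjusted over the list alone. The median was 0.55 (camera adjusted p = 2.89e-13, adjusted p = 0.464 with an estimated correlation). In nfsa 1 rose and 2 fell, with a median of -0.081. The macrophage genes Chil3 (1.28) and Ms4a7 (1.16) rose. The chemokine genes Ccl11 and Ccl7 rose by 1.15 ± 0.22 (-0.14 to 2.18) and 1.11 ± 0.12 (-0.095 to 2.67), and S100a9, a calcium-binding protein gene abundant in neutrophils, by 1.10 ± 0.18. In the floor setting Ccl7 lost its call (adjusted p = 0.0943).

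Cholesterol, glycolysis and replication genes were lower at day 1 on average. The cholesterol synthesis genes Sqle, Hmgcs1 and Lss fell (-1.0, -0.85 and -0.77), and within this list 0 of 16 rose, 14 fell and 2 did not pass, or 0 and 14 adjusted over the list alone. The median was -0.47 (camera adjusted p = 0.000221, adjusted p = 0.464 with an estimated correlation). Slc16a3, a lactate exporter gene, and Gapdh, a glycolysis gene, fell (-1.27 and -0.80), and across the hypoxia and glycolysis list 2 of 25 rose, 17 fell and 6 did not pass, or 2 and 18 adjusted over the list alone. The median was -0.34 (camera adjusted p = 0.000988, adjusted p = 0.79 with an estimated correlation). In mca4 4 rose and 5 fell. Ccne2, a cyclin of S phase entry, and Mcm7, part of the replicative helicase, fell (-0.86 and -0.69), and for DNA replication genes 1 of 30 rose, 19 fell and 10 did not pass, or 1 and 19 adjusted over the list alone. The median was -0.29 (camera adjusted p = 0.000988, adjusted p = 0.79 with an estimated correlation). The fall came from the fibrosarcomas, where 26 (radiation-induced) and 21 (nfsa) fell and 0 rose. In mmca 5 rose and 0 fell (median 0.17), and in mca4 6 rose and 4 fell (0.11). Of mitosis genes 11 of 34 rose and 7 fell (median 0.12, camera adjusted p = 0.0861). Skeletal muscle genes had a median of 0.28 in these arrays (camera adjusted p = 0.188). Other rises included the carboxylesterase gene Ces2e (2.12 ± 0.12), Sncg (1.66), the MHC class I gene H2-Q1 (1.57) and Celf5 (1.68).

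The largest falls included the olfactory receptor gene Olfr143 (-2.15 ± 0.14) and the transcription factor genes Gata5 (-2.05 ± 0.12) and Tbr1 (-1.96 ± 0.12). The receptor tyrosine kinase gene Ret (-1.44 ± 0.086) and the ceramidase gene Acer2 (-1.96 ± 0.064) fell too. In mmca and mca4, the mean log2 intensity of Tbr1 was 3.60 in unirradiated gamma arrays, 0.56 at day 1 after 30 Gy of gamma rays and 0.94 in unirradiated arrays of the carbon experiment.

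**Figure D1:**
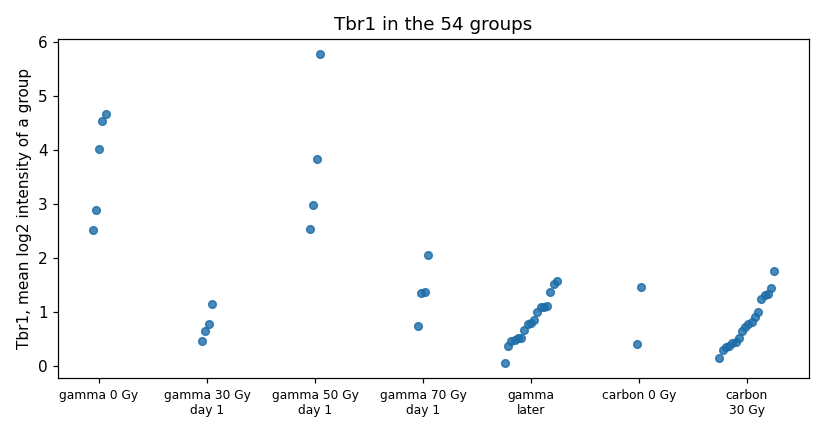
Mean log2 intensity of Tbr1 (vertical axis) in 54 groups of arrays, 1 point each, set by beam, dose and time (horizontal axis). Unirradiated gamma arrays of mmca and mca4 had a mean of 3.60 and unirradiated carbon arrays of the same tumours 0.94.

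limma called 7638 of 12848 genes (3186 higher and 4452 lower), of which 71 rose and 38 fell at least 2-fold. After quantile normalization 4241 genes were higher and 3370 lower, and with the arrays of each group averaged to 1 value 1019 genes passed, including 20 of the 30 called genes named for this comparison.

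In the radiation-induced fibrosarcoma at day 1 (6 irradiated and 2 unirradiated arrays), interferon-stimulated genes had the largest rises. Ifit1, a sensor of foreign RNA, rose by 3.52 ± 0.25, Rsad2 by 3.29 ± 0.44 and Cxcl10 by 3.20 ± 0.26. Over the interferon list, 33 of 36 rose, 1 fell and 2 did not pass, or 33 and 1 adjusted over the list alone. The median was 1.17 (camera adjusted p = 7.01e-20, adjusted p = 0.155 with an estimated correlation). p53 targets rose too, with Cdkn1a at 2.91 ± 0.16, Ephx1 at 2.46, Fas at 2.43, Mdm2 at 1.56 and Perp, a junction and apoptosis gene, at 1.75. Of the p53 list, 18 of 32 rose, 3 fell and 11 did not pass, or 18 and 3 adjusted over the list alone. The median was 0.30 (camera adjusted p = 2.18e-08, adjusted p = 0.00412 with an estimated correlation). Genes of cell division and replication that fell included Kif23 (-2.24 ± 0.23), a kinesin of cytokinesis, Ccna2 (-1.21), a cyclin, Cdc6 (-1.73), a licensing factor of replication origins, and Ccne2 (-1.77). The base excision glycosylase gene Ogg1 (-2.40 ± 0.14), the metallothionein gene Mt2 (-2.47 ± 0.21) and Sqle (-2.05 ± 0.21) fell as well. limma called 6576 genes (2391 higher, 4185 lower), against 3232 higher and 2992 lower after quantile normalization, which moved the median of all genes from -0.10 to 0.01. Averaging groups to 1 value left 4, Mt2 being the 1 called gene among those named here.

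The mmca carcinoma at day 1 (6 irradiated and 2 unirradiated arrays) had higher stromal and inflammatory genes. The monocyte chemokine genes Ccl7 and Ccl12 rose by 2.67 ± 0.24 and 2.29 ± 0.22, the complement gene C1qa by 1.59 ± 0.17, and Fcer1g, an adaptor of Fc receptors, by 1.75 ± 0.17. In the macrophage list, 15 of 24 rose, 1 fell and 8 did not pass, or 16 and 1 adjusted over the list alone. The median was 1.08 (camera adjusted p = 7.73e-10, adjusted p = 0.145 with an estimated correlation). Thbs4, a matrix thrombospondin gene, rose by 4.21 ± 0.71 and Lum, which encodes the collagen-binding lumican, by 3.21 ± 0.68. In the fibroblast and matrix list, 22 of 38 rose, 2 fell and 14 did not pass, or 25 and 2 adjusted over the list alone. The median was 0.82 (camera adjusted p = 1.89e-07, adjusted p = 0.365 with an estimated correlation). Acta1, skeletal muscle actin, rose by 3.24 ± 0.80, and the skeletal muscle list moved beside these groups: 14 of 29 rose, 0 fell and 15 did not pass, or 15 and 0 adjusted over the list alone. The median was 1.71 (camera adjusted p = 0.000188, adjusted p = 0.528 with an estimated correlation). Hypoxia genes fell, with Adm (adrenomedullin) at -2.03 ± 0.33, Ndrg1 at -1.75 and the oxygen sensor gene Egln1 at -1.59. In that list, 1 of 26 rose, 22 fell and 3 did not pass, or 1 and 22 adjusted over the list alone. The median was -0.83 (camera adjusted p = 2.05e-13, adjusted p = 0.145 with an estimated correlation).

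Mitosis genes were higher in mmca, with Pttg1 (securin) at 1.42 ± 0.19, and of that list 22 of 34 rose, 1 fell and 11 did not pass, or 22 and 1 adjusted over the list alone. The median was 0.51 (camera adjusted p = 1.83e-07, adjusted p = 0.431 with an estimated correlation). Cdkn1a rose by 1.17 ± 0.16 and Oas3, an antiviral synthetase gene, by 1.68 ± 0.17. Tfrc, the transferrin receptor gene, fell (-1.71 ± 0.19), and Mdm2 gave 0.019 (adjusted p = 0.937). limma called 4264 genes (2328 higher, 1936 lower), against 3420 and 1350 after quantile normalization. Without replicate 2 of the unirradiated day 1 group 2270 genes passed, and with 1 value per group limma called 0 (871 at an unadjusted p under 0.05). At 30 Gy alone, the dose matched in brightness, the calls of Lum (1.19), Acta1 (2) and the mitosis and muscle lists were lost, and Mdm2 fell (-0.597, adjusted p = 0.00538). The muscle list mean was 0.152 at 0 Gy, 1.10 at 30, 3.07 at 50 and 0.67 at 70, so its rise lay mostly in the 50 Gy pair. Ccl7 lost its call in the floor setting (adjusted p = 0.0803).

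In nfsa at day 1 (6 irradiated and 2 unirradiated arrays), p53 targets rose, with Cdkn1a at 1.80 ± 0.16, Ephx1 at 1.59 ± 0.15, Mdm2 at 1.37 ± 0.15 and Dcxr, a sugar reductase gene, at 1.58 ± 0.11. For p53 targets, 17 of 32 rose, 1 fell and 14 did not pass, or 17 and 2 adjusted over the list alone. The median was 0.35 (camera adjusted p = 5.32e-13, adjusted p = 3.08e-05 with an estimated correlation). The helicase genes Mcm6 (-1.16 ± 0.15) and Mcm5 (-1.06 ± 0.14) fell. S100a9 rose by 1.75 ± 0.37, while Adm (-0.94 ± 0.33) and the cystine transporter gene Slc7a11 (-1.87 ± 0.27) fell. Myh4, a fast muscle myosin gene, rose by 2.91 ± 1.10, and among skeletal muscle genes 11 of 33 rose, 2 fell and 20 did not pass, or 13 and 2 adjusted over the list alone. The median was 1.51 (camera adjusted p = 0.000334, adjusted p = 0.875 with an estimated correlation). The call of Myh4 was lost in the floor setting (adjusted p = 0.0705), at the doses matched for brightness (0.0627) and without any of 6 of the 8 arrays (highest adjusted p 0.168), that of Adm without either unirradiated array (0.0916 and 0.178) and that of Mcm6 in the floor setting (0.414). Of 12932 genes, 3753 passed (1205 higher, 2548 lower). That count was 1681 without replicate 2 of the unirradiated group and 56 with 1 value per group.

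In mca4 at day 1 (6 irradiated and 2 unirradiated arrays), Rsad2 rose by 2.60 ± 0.34, Ifit1 by 1.52 ± 0.25, Cdkn1a by 2.11 ± 0.16 and Mdm2 by 0.78 ± 0.15. Among interferon genes, 26 of 36 rose, 0 fell and 10 did not pass, or 26 and 0 adjusted over the list alone. The median was 0.60 (camera adjusted p = 2.99e-07, adjusted p = 0.932 with an estimated correlation). Aurka, a mitotic kinase gene, rose by 1.69 ± 0.16 and Pttg1 by 1.10 ± 0.19. Adm (1.97 ± 0.33) and the insulin receptor gene Insr (1.77 ± 0.16) rose, and Mt2 fell (-2.42 ± 0.21). The skeletal muscle median was -0.60 (camera adjusted p = 0.457). In the floor setting Ifit1 and Pttg1 lost their calls (adjusted p = 0.0587 and 0.142). limma called 5535 genes (2762 higher, 2773 lower), and 53 with 1 value per group.

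**Figure D2:**
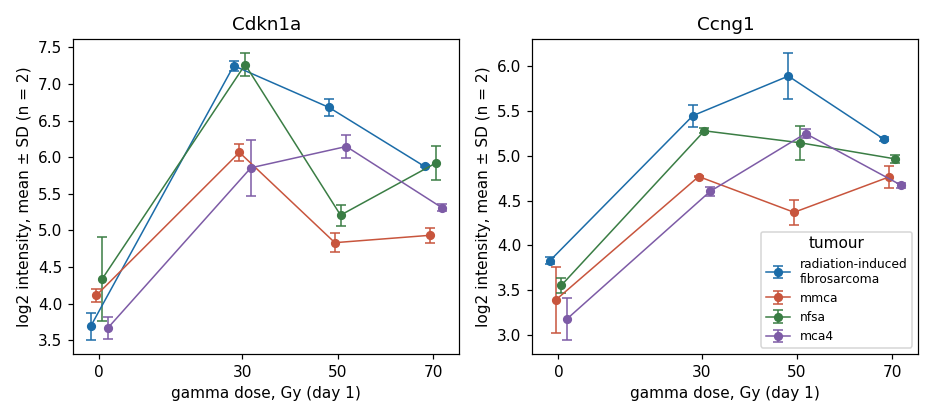
Log2 intensity (vertical axis) of Cdkn1a and Ccng1 at day 1 after each gamma dose (horizontal axis), with points for group means of 2 arrays and bars for 1 SD, coloured by tumour. Averaged over doses and tumours, Cdkn1a rose by 2.0 and Ccng1 by 1.54.

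Between 70 and 30 Gy at day 1 (8 and 8 arrays), ribosomal and respiratory chain genes were lower at the higher dose, the list of the latter not after quantile normalization. The ribosomal protein genes Rps18 (-0.76 ± 0.071) and Rpl11 (-0.74 ± 0.071) and the respiratory chain genes Uqcrb (-0.76 ± 0.081) and Cox4i1 (-0.69 ± 0.07) were lower. In the ribosomal list, 1 of 29 were higher, 26 lower and 2 did not pass, or 1 and 26 adjusted over the list alone. The median was -0.68 (camera adjusted p = 6.57e-22, adjusted p = 0.0159 with an estimated correlation). Of oxidative phosphorylation genes, 2 of 30 were higher, 24 lower and 4 did not pass, or 2 and 24 adjusted over the list alone. The median was -0.39 (camera adjusted p = 1.47e-07, adjusted p = 0.582 with an estimated correlation). After quantile normalization that list was at 0.00152 (adjusted p = 0.171) and Cox4i1 at -0.116 (adjusted p = 0.181). In the floor setting Rps18 (-0.0825) and both lists lost their calls and Uqcrb turned to 1.06. The interferon-induced genes Cxcl10 (-1.29 ± 0.16) and Oasl1 (-1.01 ± 0.12) were lower too. Ctr9, part of a transcription elongation complex, was higher (4.66 ± 0.079), with 0.72 to 6.57 across tumours. Its log2 intensity was 5.67 to 6.83 at 70 Gy in 3 tumours and at most 1.56 in every other group, and a fault of the probe or the array run was not tested. Also higher were Adcy10 (1.65 ± 0.15) and Kif23 (1.11 ± 0.14). Reg3g (-1.62 ± 0.36) and the kinase gene Pim1 (-1.46 ± 0.11) were lower. The muscle troponin gene Tnnc2 gave -1.35 ± 0.59 (adjusted p = 0.0493), a call lost without any 1 of the 16 arrays (adjusted p up to 0.076), after quantile normalization (0.154), with the replicate block (0.061) and in the floor setting (0.183), and the skeletal muscle list had a median of -0.37. limma called 6488 genes (3067 higher, 3421 lower), against 6213 and 1113 after quantile normalization, which moved the median of all genes from -0.0098 to 0.17. Averaged to 1 value per group, 40 genes passed, with Rps18 alone among those named here.

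The response at day 1 differed between tumour types (16 fibrosarcoma and 16 mammary carcinoma arrays, each change taken against its own unirradiated group). The change of replication and mitosis genes was lower in fibrosarcomas, as for Mcm10 (-1.39 ± 0.15), Mcm5 (-1.37 ± 0.14), Cdc6 (-1.25 ± 0.16), the topoisomerase gene Top2a (-0.92) and Ccna2 (-1.02). For DNA replication genes, 0 of 30 were higher, 26 lower and 4 did not pass, or 0 and 30 adjusted over the list alone. The median was -0.79 (camera adjusted p = 2.09e-24, adjusted p = 0.0466 with an estimated correlation). For mitosis genes, 0 of 34 were higher, 30 lower and 4 did not pass, or 0 and 31 adjusted over the list alone. The median was -0.69 (camera adjusted p = 2.2e-17, adjusted p = 0.18 with an estimated correlation). The p53 targets Perp (1.36 ± 0.22), Ephx1 (1.2 ± 0.15) and Mdm2 (1.06 ± 0.15) changed by more in fibrosarcomas, and of that list 8 of 32 were higher, 0 lower and 24 did not pass, or 8 and 0 adjusted over the list alone. The median was 0.13 (camera adjusted p = 2.56e-07, adjusted p = 0.0131 with an estimated correlation). The chemokine genes Ccl7 (-1.65) and Ccl2 (-1.48), the Wnt antagonist gene Sfrp1 (-1.65), the basal keratin gene Krt5 (-1.42) and the cholesterol gene Idi1 (-1.01) had lower changes, and the ligand gene Wnt4 (1.55) a higher one. Skeletal muscle genes differed by a median of -0.14. limma called 2812 genes (561 higher, 2251 lower), against 1650 in the floor setting, where Ccl7 (adjusted p = 0.467) and Cdc6 (0.0882) lost their calls. With 1 value per group limma called 0 (575 at an unadjusted p under 0.05). In a simpler model another grouping of the 4 tumours gave more genes than the tumour types (1143 against 216).

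From day 8 to day 25 after gamma rays, genes of immune cells rose in the mean of 4 tumours (27 irradiated and 8 unirradiated arrays). T and NK cell genes rose, with Cd3g, a T cell receptor chain, at 2.14 ± 0.25 (1.61 to 2.53 across tumours), Klrc1 and Klra3, NK cell receptors, at 2.54 ± 0.18 and 2.14 ± 0.16, Nkg7 at 1.86 and the perforin gene Prf1 at 1.82. Of the T and NK list, 16 of 19 rose, 1 fell and 2 did not pass, or 16 and 1 adjusted over the list alone. The median was 1.39 (camera adjusted p = 0.000229, adjusted p = 0.352 with an estimated correlation). Mpeg1 (1.78 ± 0.11), Cd83 (2.03 ± 0.13), the apolipoprotein gene Apoe (2.94 ± 0.17) and the macrophage elastase gene Mmp12 (2.70 ± 0.18) also rose, and of macrophage markers 19 of 24 rose, 2 fell and 3 did not pass, or 19 and 2 adjusted over the list alone. The median was 0.97 (camera adjusted p = 5.86e-07, adjusted p = 0.352 with an estimated correlation). In the radiation-induced fibrosarcoma 10 rose and 3 fell. The complement genes C2 and Cfb rose by 1.78 ± 0.16 and 1.53 ± 0.15.

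Interferon-induced GTPase genes rose, with Gbp8 at 3.04 ± 0.22, Gbp2 at 2.43 ± 0.14 and Iigp1 at 2.20 ± 0.15, and Rsad2 at 2.26 ± 0.18 (-0.39 to 4.39 across tumours). In the late interferon list, 32 of 36 rose, 1 fell and 3 did not pass, or 32 and 1 adjusted over the list alone. The median was 0.93 (camera adjusted p = 7.46e-12, adjusted p = 0.352 with an estimated correlation). Jchain, which joins secreted antibodies, rose by 3.50 ± 0.48 and Ighm, the IgM heavy chain, by 1.44 ± 0.15. Ltf, the lactoferrin gene, rose by 2.33 ± 0.15 (0.26 to 4.42 across tumours) and the alarmin gene Il33 by 1.59 ± 0.17. The skeletal muscle list had a median of -0.20 (camera adjusted p = 0.785).

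Among p53 targets at these days, Fas rose by 1.51 ± 0.074, Mdm2 by 1.31 ± 0.073 (0.37 to 2.01 across tumours), Ccng1 by 0.54 ± 0.069 and Cdkn1a by 0.52 ± 0.078 (-0.41 to 1.44), and Trp53inp1 fell (-0.21 ± 0.049). In the p53 target list, 17 of 32 rose, 6 fell and 9 did not pass, or 17 and 6 adjusted over the list alone. The median was 0.16 (camera adjusted p = 0.0197, adjusted p = 0.369 with an estimated correlation). The cholesterol genes Lss (-0.86 ± 0.07) and Mvd (-0.86 ± 0.088) fell. Rpl19 rose (0.39 ± 0.05, -0.28 to 0.80), but not in the floor setting (0.107, adjusted p = 0.829). Olfr143 (-3.61 ± 0.14) and Tbr1 (-3.15 ± 0.12), both high on unirradiated gamma arrays, had the largest falls. limma called 9480 of 12889 genes (4382 higher, 5098 lower), of which 417 rose and 158 fell at least 2-fold. In the floor setting 4770 were higher and 4528 lower. The count with 1 value per group was 3528, including 26 of the 29 named genes. Outside mmca, dimmest values lay at 0.0785 to 0.11 on unirradiated and 0.11 to 0.182 on late arrays. In mmca they overlapped. Array brightness or run thus stays open, and so does time since day 1 outside mmca.

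**Figure D3:**
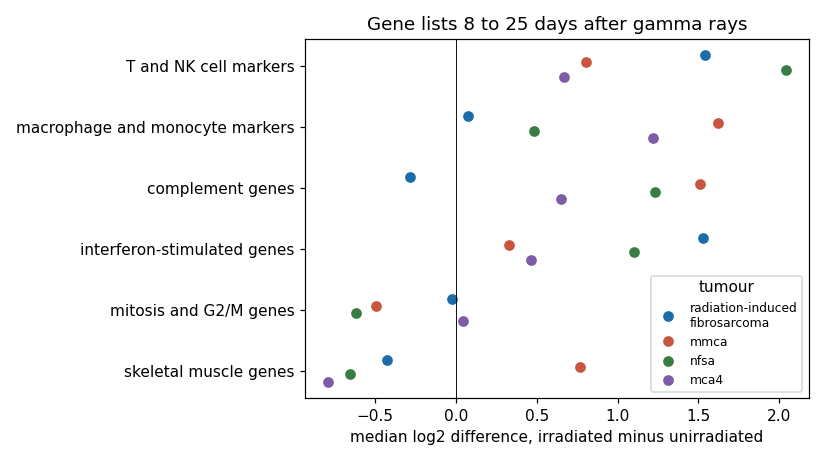
Median log2 difference between irradiated tumours of days 8 to 25 and unirradiated tumours (horizontal axis) for 6 gene lists (vertical axis), with 1 point per tumour. The median over T and NK cell markers was 1.54 in the radiation-induced fibrosarcoma, 0.80 in mmca, 2.04 in nfsa and 0.67 in mca4.

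In the late radiation-induced fibrosarcoma (9 irradiated and 2 unirradiated arrays), Jchain rose by 4.98 ± 0.92, Rsad2 by 4.39 ± 0.43, the granzyme gene Gzmb by 2.90 ± 0.29, Cd3g by 2.53 ± 0.48 and Cxcr6, a chemokine receptor of T cells, by 3.60 ± 0.41. For interferon genes there, 31 of 36 rose, 0 fell and 5 did not pass, or 32 and 1 adjusted over the list alone. The median was 1.53 (camera adjusted p = 2.2e-14, adjusted p = 0.44 with an estimated correlation). The hypoxia genes Adm (3.62 ± 0.31) and P4ha2, a collagen prolyl hydroxylase (2.50 ± 0.18), rose. Cdkn1a rose by 1.44 ± 0.15 and Mdm2 by 2.01 ± 0.14, while Sfrp1 fell (-3.51 ± 0.29). Muscle genes had a median of -0.43 in this comparison. limma called 8749 genes (3635 higher, 5114 lower), and 1910 with 1 value per group, including 4 of the 10 named ones.

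In late mmca (6 irradiated and 2 unirradiated arrays of day 9), basal epithelial and myeloid genes rose. Krt5 and Krt14, keratins of basal epithelium, rose by 4.16 ± 0.30 and 2.79 ± 0.24, the coagulation factor gene F5 by 4.47 ± 0.46 and Ltf by 4.15 ± 0.31. In the epithelial list, 15 of 27 rose, 2 fell and 10 did not pass, or 15 and 2 adjusted over the list alone. The median was 0.57 (camera adjusted p = 0.000471, adjusted p = 0.111 with an estimated correlation). Mrc1, the macrophage mannose receptor, rose by 3.25 ± 0.30, and of macrophage markers in late mmca 19 of 24 rose, 0 fell and 5 did not pass, or 21 and 1 adjusted over the list alone. The median was 1.62 (camera adjusted p = 1.25e-14, adjusted p = 0.0294 with an estimated correlation). Cd74, the MHC class II invariant chain, rose by 2.43 ± 0.46. Decorin (Dcn) rose by 3.15 ± 0.46. Skeletal muscle genes had a median of 0.77 beside these groups (camera adjusted p = 0.174).

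The mitotic kinase gene Plk1 (-0.97 ± 0.16) and the cytokine-like gene Cytl1 (-3.06 ± 0.31) fell in late mmca, and of mitosis genes 0 of 34 rose, 23 fell and 11 did not pass, or 0 and 24 adjusted over the list alone. The median was -0.49 (camera adjusted p = 2.25e-08, adjusted p = 0.293 with an estimated correlation). Cdkn1a (0.43 ± 0.16, adjusted p = 0.0223) and Mdm2 (0.37 ± 0.15, adjusted p = 0.0368) passed by little. Leaving out replicate 2 of the unirradiated group moved Mdm2 to 0.0907 (adjusted p = 0.769), and leaving out replicate 1 moved Cdkn1a to 0.34 (adjusted p = 0.222). Mdm2 lost its call in 4 such fits and from these arrays alone (0.0973), and Cdkn1a in 3, after quantile normalization (0.198), with the replicate block (0.332, adjusted p = 0.0944) and in the floor setting (0.131). With array weights both lost it (0.0509 and 0.0513). Set against the day 1 unirradiated group instead, Plk1 gave -0.0117 (adjusted p = 0.962), Mdm2 turned to -0.0818, and the epithelial and mitosis calls were lost (adjusted p = 0.0651 and 0.0963). limma called 5490 genes (3318 higher, 2172 lower), against 2202 and 4469 after quantile normalization, which moved the median of all genes from 0.039 to -0.13. Without replicate 2 of the day 9 unirradiated group the count was 3556, and with 1 value per group limma called 0 (1059 at an unadjusted p under 0.05).

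In late nfsa (6 irradiated and 2 unirradiated arrays), the granzyme genes Gzma and Gzmg rose by 3.72 ± 0.37 and 3.81 ± 0.72, Prf1 by 3.30 ± 0.37 and Apoe by 4.86 ± 0.35. The interferon-inducible GTPase gene Iigp1 rose by 3.19 ± 0.31. Mcm5 (-1.70 ± 0.14) and Plk1 (-1.69 ± 0.16) fell. Mmp9 fell (-2.99 ± 0.25) and Mdm2 rose (0.96 ± 0.15). Cdkn1a gave -0.41 ± 0.16 (adjusted p = 0.0229), but -0.00463 (adjusted p = 0.987) without unirradiated replicate 1 and -0.325 (0.0748) without replicate 3 of 30 Gy day 9, and it lost its call from these arrays alone (0.145) and in the floor setting (0.0951). Muscle genes had a median of -0.66 in late nfsa. limma called 7436 genes (3172 higher, 4264 lower), against 2186 and 5614 after quantile normalization, which moved the median of all genes from -0.065 to -0.20. With 1 value per group limma called 0 (2169 at an unadjusted p under 0.05).

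In late mca4 (6 irradiated and 2 unirradiated arrays), Ltf rose by 4.42 ± 0.31, F5 by 3.61 ± 0.34, the calcium-binding gene S100g by 3.61 ± 0.40, Mmp12 by 3.23 ± 0.35, Cxcr6 by 3.12 ± 0.43 and Gbp2 by 2.49 ± 0.28. Mdm2 rose by 1.91 ± 0.15 and Cdkn1a by 0.59 ± 0.16, while parvalbumin (Pvalb), a calcium buffer of fast muscle, gave -4.04 ± 1.46 (adjusted p = 0.0129), a call lost with the replicate block (-3.28, adjusted p = 0.0817), from these arrays alone (0.058) and without either unirradiated array (0.0693 and 0.0752). The skeletal muscle median was -0.79 in late mca4. limma called 8253 genes (3705 higher, 4548 lower), and 4187 with 1 value per group. After quantile normalization 4476 were higher and 3795 lower, with the median of all genes moved from -0.057 to 0.045.

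At 6 hours after 30 Gy of carbon ions, mitosis genes had fallen in mmca and mca4 (4 irradiated and 4 unirradiated arrays). The mitotic kinases Plk1 (-1.61 ± 0.14) and Aurka (-1.51 ± 0.14), Cdc20, an activator of the anaphase-promoting complex (-1.56 ± 0.13), Aspm (-1.36 ± 0.12) and the helicase gene Pif1 (-2.44 ± 0.13) were lower. In the mitosis list, 0 of 34 rose, 31 fell and 3 did not pass, or 0 and 33 adjusted over the list alone. The median was -0.94 (camera adjusted p = 1.63e-57, adjusted p = 0.000231 with an estimated correlation). The p53 targets Dcxr (1.29 ± 0.096), Ccng1 (1.10 ± 0.12), Cdkn1a (1.06 ± 0.14) and Btg2 (0.99 ± 0.18) rose, and of their list 15 of 32 rose, 0 fell and 17 did not pass, or 18 and 1 adjusted over the list alone. The median was 0.33 (camera adjusted p = 2.5e-16, adjusted p = 1.71e-06 with an estimated correlation). Mdm2 gave 0.31 ± 0.13 (adjusted p = 0.119) and Trp53inp1 -0.014 (adjusted p = 0.949), the latter 0.0275 after quantile normalization, while Mdm2 passed with array weights (0.0131) and from these arrays alone (0.0274). Inflammatory genes rose, with the pentraxin gene Ptx3 at 2.90 ± 0.35, the neutrophil chemokine genes Cxcl2 and Cxcl3 at 2.12 ± 0.28 and 2.13 ± 0.32, Ccl3 at 1.73, Ccl2 at 1.44 and the proteases Mmp3 and Mmp8 at 1.91 and 1.86. Of chemokines and cytokines, 10 of 29 rose, 0 fell and 19 did not pass, or 11 and 0 adjusted over the list alone. The median was 0.23 (camera adjusted p = 1.68e-08, adjusted p = 0.0238 with an estimated correlation).

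The cholesterol genes Mvd (-0.77 ± 0.15) and Sqle (-0.67 ± 0.18) and the chaperone gene Hsph1 (-0.77 ± 0.16) fell at hour 6, and of the cholesterol list 0 of 16 rose, 11 fell and 5 did not pass, or 0 and 13 adjusted over the list alone. The median was -0.49 (camera adjusted p = 2.05e-08, adjusted p = 0.0836 with an estimated correlation). Krt14 rose (0.91 ± 0.21). Sqle lost its call without unirradiated mca4 replicate 1 (adjusted p = 0.0503) or irradiated mca4 replicate 2 (0.0697), and Hsph1 in the floor setting (0.0862). The cardiac and slow muscle gene Myl2 fell (-2.40 ± 0.49), and the skeletal muscle list had a median of -0.96 with 4 of 33 genes lower (camera adjusted p = 0.000183, adjusted p = 0.609 with an estimated correlation). limma called 1236 of 12955 genes (655 higher, 581 lower). The count was 721 without replicate 1 of unirradiated mmca, 3377 from these arrays alone (1594 higher, 1783 lower) and 315 with 1 value per group.

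At day 1 after carbon ions (4 irradiated and 4 unirradiated arrays), the p53 targets Dcxr (1.0 ± 0.096), Cdkn1a (0.94 ± 0.14) and Ccng1 (0.78 ± 0.12) remained above the unirradiated arrays. Mdm2 gave 0.39 ± 0.13 (adjusted p = 0.0446), a call lost after quantile normalization (adjusted p = 0.363) and without any of 7 of the 8 arrays (up to 0.21), and Trp53inp1 gave -0.14 (adjusted p = 0.341). Over the p53 list, 11 of 32 rose, 0 fell and 21 did not pass, or 15 and 0 adjusted over the list alone. The median was 0.22 (camera adjusted p = 3.14e-09, adjusted p = 0.00174 with an estimated correlation). The antiviral genes Oas3 (0.96 ± 0.15) and Isg20 (1.02 ± 0.17) and the chemokine gene Ccl5 (1.27 ± 0.29) rose. Chil3 (1.57 ± 0.28) and Ces2e (1.55 ± 0.21) rose. Lss (-0.71 ± 0.12), Mvd (-0.73 ± 0.15), the cyclin gene Ccne1 (-0.73 ± 0.14), Ero1a (-0.74 ± 0.20), an oxidase of protein folding, the heat shock gene Hspa1a (-1.78 ± 0.32) and Ighm (-1.59 ± 0.27) fell, Ccne1 not in the floor setting (adjusted p = 0.159).

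At day 1 after carbon ions, skeletal muscle genes had a median of 0.83, with 0 of 33 passing (camera adjusted p = 0.0109, adjusted p = 0.627 with an estimated correlation). limma called 1036 of 12954 genes (540 higher, 496 lower). Leaving out replicate 2 of unirradiated mca4 gave 570, fitting these arrays alone 3590 and 1 value per group 142.

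At day 3 after carbon ions (4 irradiated and 4 unirradiated arrays), epithelial and myeloid genes rose in both mammary carcinomas. Sprr1a, a precursor of the cornified envelope, rose by 3.33 ± 0.29, Ly6d by 3.07 ± 0.21, Krt14 by 2.37 ± 0.21, Ltf by 3.01 ± 0.27 and the cystatin gene Stfa3 by 2.57 ± 0.24. In the epithelial list at day 3, 16 of 27 rose, 2 fell and 9 did not pass, or 16 and 2 adjusted over the list alone. The median was 0.45 (camera adjusted p = 2.53e-08, adjusted p = 0.00407 with an estimated correlation). Mmp12 (2.48 ± 0.31), Chil3 (2.26 ± 0.28) and the scavenger receptor gene Msr1 (1.70 ± 0.12) rose, and of macrophage markers 19 of 24 rose, 0 fell and 5 did not pass, or 20 and 0 adjusted over the list alone. The median was 1.19 (camera adjusted p = 1.71e-15, adjusted p = 0.0143 with an estimated correlation). The chemokine genes Ccl7 (2.32 ± 0.21) and Ccl2 (2.04 ± 0.18) and the growth factor gene Csf2 (1.93 ± 0.23) rose, Ccl7 not in the floor setting (adjusted p = 0.0632). C2 rose by 1.53 ± 0.28, Gzma by 2.26 ± 0.32 and Oas3 by 1.5 ± 0.15.

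Cholesterol synthesis genes were lower at day 3. Idi1 fell (-1.89 ± 0.22), and in the cholesterol list 0 of 16 rose, 15 fell and 1 did not pass, or 0 and 15 adjusted over the list alone. The median was -1.11 (camera adjusted p = 1.68e-11, adjusted p = 0.0225 with an estimated correlation). The mitotic checkpoint gene Bub1b (-0.95 ± 0.18) and Uhrf1, which maintains DNA methylation (-0.96 ± 0.12), fell. Adm (-1.40 ± 0.28) and the angiogenic factor gene Vegfa (-1.30 ± 0.19) fell. Cytl1 (-2.55 ± 0.27) and Hspa1a (-2.43 ± 0.32) were also lower. Fas (1.34 ± 0.13), Cdkn1a (1.01 ± 0.14), Ccng1 (0.66 ± 0.12) and Mdm2 (0.57 ± 0.13) rose, and Trp53inp1 gave -0.12 (adjusted p = 0.271). For p53 targets at day 3, 18 of 32 rose, 3 fell and 11 did not pass, or 18 and 3 adjusted over the list alone. The median was 0.39 (camera adjusted p = 1.06e-05, adjusted p = 0.0188 with an estimated correlation). Muscle genes had a median of -0.32. limma called 5558 of 12948 genes (2239 higher, 3319 lower), and 4273 with 1 value per group. In the floor setting the split was 2328 higher and 2261 lower.

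By day 5 after carbon ions (4 irradiated and 4 unirradiated arrays), the rises in epithelial and immune genes were large. Ltf rose by 4.71 ± 0.27, Sprr1a by 4.21 ± 0.29, Ly6d by 4.09 ± 0.21, Krt14 by 3.26 ± 0.21 and Krt5 by 3.07 ± 0.26. In the epithelial list at day 5, 17 of 27 rose, 2 fell and 8 did not pass, or 17 and 2 adjusted over the list alone. The median was 0.73 (camera adjusted p = 4.32e-08, adjusted p = 0.00475 with an estimated correlation). Mrc1 rose by 2.38 ± 0.26, Ccl8 by 2.44 ± 0.34 and Csf2 by 3.07 ± 0.23, and of macrophage markers 24 of 24 rose, 0 fell and 0 did not pass, or 24 and 0 adjusted over the list alone. The median was 1.69 (camera adjusted p = 7.85e-16, adjusted p = 0.0191 with an estimated correlation). C1qa rose by 1.69 ± 0.15. Cd3g (2.44 ± 0.44), Nkg7 (2.24 ± 0.37) and Prf1 (2.13 ± 0.32) rose, and of T and NK markers 16 of 19 rose, 1 fell and 2 did not pass, or 16 and 1 adjusted over the list alone. The median was 1.76 (camera adjusted p = 1.26e-06, adjusted p = 0.0797 with an estimated correlation). The MHC class II gene H2-Ab1 rose by 1.80 ± 0.31.

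Mitosis genes fell as a group at day 5. Bub1b (-1.57 ± 0.16) and Uhrf1 (-1.55 ± 0.12) were lower. Of mitosis genes, 0 of 34 rose, 34 fell and 0 did not pass, or 0 and 34 adjusted over the list alone. The median was -1.07 (camera adjusted p = 2.65e-12, adjusted p = 0.125 with an estimated correlation). Sqle (-2.06 ± 0.18) and Idi1 (-2.08 ± 0.22) fell. Vegfa (-1.72 ± 0.19) and Bnip3, a mitophagy receptor gene (-1.66 ± 0.18), fell. Cytl1 (-5.53 ± 0.27) and Hspa1a (-2.73 ± 0.32) were far lower. Pmaip1, which encodes the apoptosis inducer Noxa, rose (1.57 ± 0.13), as did Cdkn1a (0.91 ± 0.14), Mdm2 (0.73 ± 0.13) and Ccng1 (0.63 ± 0.12), while Trp53inp1 gave -0.22 ± 0.086 (adjusted p = 0.025), a call lost after quantile normalization (adjusted p = 0.335), from these arrays alone (0.053) and without any of 4 arrays, unirradiated mmca replicate 1 giving -0.112 (0.306). Muscle genes had a median of 0.70 at day 5. limma called 7844 of 12952 genes (2862 higher, 4982 lower), with 3311 and 3651 in the floor setting. From 1 value per group 6947 passed, including 25 of the 26 named genes.

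**Figure D4:**
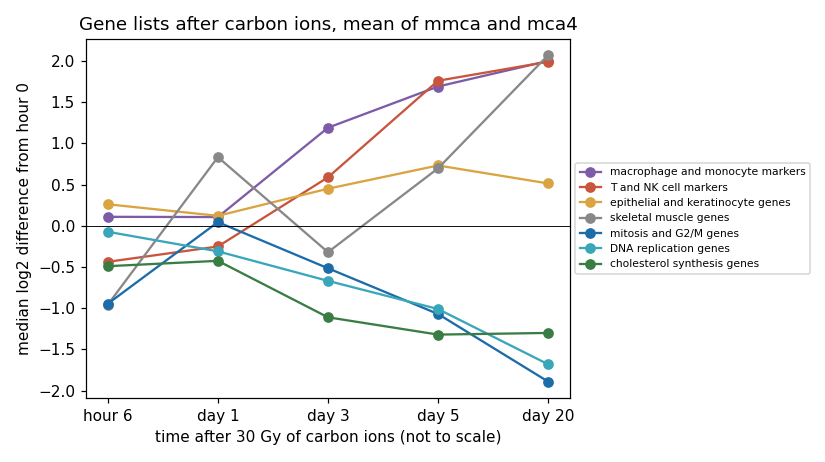
Median log2 difference from unirradiated arrays (vertical axis) for 7 gene lists at 5 times after 30 Gy of carbon ions (horizontal axis, not to scale), averaged over mmca and mca4. The median over mitosis genes was -0.94 at hour 6, 0.045 at day 1, -1.07 at day 5 and -1.89 at day 20.

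At day 20 after carbon ions (4 irradiated and 4 unirradiated arrays, the latter of hour 0), mitosis genes had the largest fall of the 5 times in mmca and mca4. Bub1b (-2.44 ± 0.16), the mitotic motility gene Hmmr (-2.35 ± 0.13), Uhrf1 (-2.42 ± 0.12) and Cdc6 (-2.13 ± 0.14) were lower. For mitosis genes at day 20, 0 of 34 rose, 34 fell and 0 did not pass, or 0 and 34 adjusted over the list alone. The median was -1.89 (camera adjusted p = 1.42e-19, adjusted p = 0.122 with an estimated correlation). F5 rose by 7.21 ± 0.30, S100g by 6.25 ± 0.34, Ltf by 6.10 ± 0.27 and Ly6d by 4.49 ± 0.21. Cd3g (3.69 ± 0.44) and Nkg7 (3.10 ± 0.37) rose. The MHC class II genes H2-Ea (3.21 ± 0.27) and H2-Ab1 (2.86 ± 0.31) rose. Lyz2, macrophage lysozyme, rose by 2.80 ± 0.19.

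Mmp3 (3.08 ± 0.29) and the thrombospondin gene Thbs2 (2.30 ± 0.20) rose at day 20. Skeletal muscle genes rose beside them, with the myosin-binding gene Mybpc2 at 3.43 ± 0.89: 28 of 33 rose, 0 fell and 5 did not pass, or 28 and 0 adjusted over the list alone. The median was 2.07 (camera adjusted p = 0.000189, adjusted p = 0.42 with an estimated correlation). The oxygen sensor gene Egln3 (-2.43 ± 0.15), Vegfa (-2.28 ± 0.19), Tfrc (-2.14 ± 0.16) and Sqle (-2.30 ± 0.18) fell, as did Cytl1 (-3.99 ± 0.27). Pmaip1 (1.85 ± 0.13) and Cdkn1a (0.74 ± 0.14) rose, Trp53inp1 fell (-0.26 ± 0.086), and Mdm2 (-0.21, adjusted p = 0.125) and Ccng1 (0.09, adjusted p = 0.51) did not pass. After quantile normalization Mdm2 gave 0.00178 and Trp53inp1 lost its call (adjusted p = 0.152), as it did without unirradiated mmca replicate 1 (-0.152, adjusted p = 0.14). Mdm2 passed from these arrays alone (-0.214, adjusted p = 0.0477). limma called 9198 of 12955 genes (3536 higher, 5662 lower), of which 1418 rose and 1063 fell at least 2-fold. The count was 8482 with 1 value per group, including 24 of the 24 called genes named for this comparison.

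The carbon responses of mmca and mca4 over days 1 to 5 were set against each other (8 arrays added and 8 subtracted). The change in mmca was higher for Enkur (2.75 ± 0.43), the protease inhibitor gene Serpinb2 (2.04 ± 0.51), the matrix signalling gene Ccn1 (1.60 ± 0.22), the claudin gene Cldn4 (1.24 ± 0.31) and the laminin gene Lamb3 (0.91 ± 0.24). In the epithelial list, 3 of 27 were higher, 0 lower and 24 did not pass, or 7 and 0 adjusted over the list alone. The median was 0.43 (camera adjusted p = 9.22e-11, adjusted p = 0.000158 with an estimated correlation). The change was lower for Mcm5 (-0.96 ± 0.20), the DNA repair gene Fanca (-0.81 ± 0.18), the embryonic myosin gene Myh3 (-2.51 ± 0.54) and the fatty acid carrier gene Fabp7 (-2.02 ± 0.24). Skeletal muscle genes differed by a median of -0.19. limma called 74 genes (51 higher, 23 lower). After quantile normalization Serpinb2 (adjusted p = 0.0788), Fanca (0.0976) and Myh3 (0.0633) lost their calls, and in the floor setting Lamb3 did (0.203). Leaving out 1 array ended the call of Lamb3 in 15 fits, Serpinb2 in 12, Cldn4 in 10, Fanca and Mcm5 in 3 and Myh3 in 2 (adjusted p up to 0.403). The count was 12 without replicate 2 of unirradiated mmca, 216 (102 higher, 114 lower) in the floor setting, 1711 (646 and 1065) from these arrays alone, 1481 (451 and 1030) with array weights and 0 with 1 value per group in limma (168 at an unadjusted p under 0.05).

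Carbon ions and gamma rays, both at 30 Gy and day 1 in mmca and mca4, were compared through each beam's change from its own unirradiated arrays (8 arrays added and 8 subtracted). The change after carbon ions was lower for the interferon-induced chemokines Cxcl10 (-1.60 ± 0.32) and Cxcl11 (-1.56 ± 0.41), H2-Q1 (-1.63 ± 0.26), the macrophage gene Ly86 (-1.45 ± 0.27), Aurka (-1.09 ± 0.20), the primase gene Prim1 (-0.91 ± 0.19) and Mcm2 (-0.82 ± 0.16). Sdhd (-0.85 ± 0.16), a respiratory chain gene, and Rplp1 (-1.19 ± 0.23), a ribosomal protein gene, had lower changes too. In the floor setting Aurka (adjusted p = 0.198), Prim1 (0.513) and H2-Q1 (0.0698) lost their calls. Tbr1 had a higher change (3.37 ± 0.31), and skeletal muscle genes differed by a median of 0.57.

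limma called 3290 genes between the beams (1537 higher, 1753 lower), against 5055 from these arrays alone. With 1 value per group limma called 0 (702 at an unadjusted p under 0.05). The unirradiated arrays of both experiments differed in 7073 genes, and beam and experiment cannot be separated.

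From day 5 to the last carbon group (day 20, or day 42 in scc7), lymphocyte genes were lower in the mean of 6 tumours (12 and 12 arrays). Gzma (-4.03 ± 0.19), Gzmb (-2.05 ± 0.15), the NK receptor gene Ncr1 (-2.73 ± 0.12) and Prf1 (-1.74 ± 0.18, -3.24 to 0.23 across tumours) fell, and of T and NK markers 0 of 19 rose, 14 fell and 5 did not pass, or 0 and 14 adjusted over the list alone. The median was -1.0 (camera adjusted p = 3.06e-13, adjusted p = 0.00561 with an estimated correlation). In mmca and mca4, though, the T and NK median against unirradiated arrays was 1.76 at day 5 and 1.99 at day 20. Mx1 (-1.09 ± 0.11), Cxcl9 (-1.61 ± 0.19) and Chil3 (-1.60 ± 0.16) fell. In the interferon list, 1 of 36 rose, 31 fell and 4 did not pass, or 1 and 32 adjusted over the list alone. The median was -0.43 (camera adjusted p = 8.63e-14, adjusted p = 0.149 with an estimated correlation). The endothelial genes Vwf (-1.04 ± 0.14, -2.03 to 0.42 across tumours) and Plvap (-0.93 ± 0.11) fell. Mdm2 (-0.78 ± 0.073) and Cdkn1a (-0.77 ± 0.079) were lower late, and of p53 targets 5 of 32 rose, 20 fell and 7 did not pass, or 5 and 20 adjusted over the list alone. The median was -0.30 (camera adjusted p = 3e-07, adjusted p = 0.00771 with an estimated correlation).

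Hypoxia genes were higher in the last group, with the carbonic anhydrase gene Car9 at 1.37 ± 0.13 (-1.06 to 3.04 across tumours), Adm at 1.34 ± 0.16 (-1.06 to 3.62) and Bnip3 at 1.13 ± 0.10 (-0.78 to 2.65). Of the hypoxia list, 24 of 26 rose, 0 fell and 2 did not pass, or 24 and 0 adjusted over the list alone. The median was 0.65 (camera adjusted p = 5.62e-15, adjusted p = 0.0794 with an estimated correlation). The cholesterol genes Idi1 (1.16 ± 0.13, -0.21 to 2.12) and Fdps (1.04 ± 0.094, -0.045 to 1.96) rose. The mast cell proteases Mcpt4 (1.10 ± 0.15, -0.32 to 3.93 across tumours) and Cpa3 (1.05 ± 0.17, -0.96 to 2.98) and the B cell chemokine gene Cxcl13 (2.41 ± 0.29, 0.70 to 4.03) rose on average, and of mast cell markers 7 of 9 rose, 1 fell and 1 did not pass, or 8 and 1 adjusted over the list alone. The median was 0.64 (camera adjusted p = 5.66e-05, adjusted p = 0.0237 with an estimated correlation). The skeletal muscle median was 0.14. limma called 5629 genes (3509 higher, 2120 lower), with 2471 and 2409 in the floor setting, and 0 with 1 value per group (1566 at an unadjusted p under 0.05).

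Between day 4 and day 9 after gamma rays in nfsa (6 and 6 arrays), hypoxia genes rose. Car9 rose by 2.22 ± 0.18, with 0.049 to 4.39 across the doses, Adm by 1.43 ± 0.23 and the glucose transporter gene Slc2a1 by 1.26 ± 0.13. In the nfsa hypoxia list, 21 of 25 rose, 0 fell and 4 did not pass, or 21 and 0 adjusted over the list alone. The median was 0.61 (camera adjusted p = 1.41e-26, adjusted p = 0.00823 with an estimated correlation). Aspm (0.71 ± 0.099) and Prc1 (0.60 ± 0.11), genes of the mitotic spindle, rose. Cdkn1a (-1.12 ± 0.11) and Mdm2 (-0.83 ± 0.10) fell. Gzma (-2.34 ± 0.26), Gzmb (-1.57 ± 0.21), Ncr1 (-1.44 ± 0.17), Chil3 (-2.05 ± 0.23) and the endothelial genes Egfl7 (-1.11 ± 0.13) and Sox18 (-1.03 ± 0.15) fell. Cxcl13 (1.75 ± 0.41) and the enkephalin gene Penk (1.69 ± 0.28) rose. Muscle genes had a median of -0.31 between these days. limma called 2663 genes (1452 higher, 1211 lower), 1272 from these arrays alone (629 and 643), and 0 with 1 value per group (986 at an unadjusted p under 0.05).

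After 50 Gy of gamma rays, the last group was set against the earlier one in mca4 (day 41 and day 25) and scc7 (day 35 and day 23), with 4 and 5 arrays. Vegfa rose by 1.29 ± 0.18, Adm by 1.26 ± 0.27, Hspa1a by 1.56 ± 0.30, S100a9 by 2.20 ± 0.31, the early response gene Fos by 1.25 ± 0.20, Srebf2, a regulator of cholesterol genes, by 0.90 ± 0.12, Plk1 by 0.51 ± 0.14 and Rpl11 by 0.37 ± 0.096 (-0.087 to 0.83). Of hypoxia genes, 20 of 26 rose, 0 fell and 6 did not pass, or 21 and 0 adjusted over the list alone. The median was 0.58 (camera adjusted p = 3.71e-15, adjusted p = 0.158 with an estimated correlation). Lum (-2.82 ± 0.56) and periostin (Postn, -1.64 ± 0.26) fell. Mrc1 (-1.53 ± 0.25) and C1qa (-0.66 ± 0.14) fell. Acta1 fell (-2.23 ± 0.66), and the muscle list moved beside these groups, in which 0 of 33 rose, 8 fell and 25 did not pass, or 0 and 11 adjusted over the list alone. The median was -1.09 (camera adjusted p = 6.83e-07, adjusted p = 0.458 with an estimated correlation).

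limma called 2357 genes between these days (1130 higher, 1227 lower), and 18 from these 9 arrays alone, where 12 of the 13 genes named for this comparison did not pass. Acta1 was at -0.47 (adjusted p = 0.632) without replicate 2 of scc7 at day 35 and lost its call without mca4 day 41 replicate 2 (0.121) or scc7 day 23 replicate 1 (0.0674), Adm was at 0.732 (0.0755) without scc7 day 35 replicate 1 and Plk1 at 0.353 (0.122) without scc7 day 23 replicate 2. Rpl11 lost its call after quantile normalization (0.299). Leaving out replicate 2 of mca4 at day 41 gave 1217 genes, leaving out replicate 1 of mca4 at day 25 gave 3022, and with 1 value per group limma called 0 (754 at an unadjusted p under 0.05). The split was 685 higher and 1866 lower after quantile normalization, and 2671 and 1780 testing every probe.

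Before irradiation, the fibrosarcomas differed widely from the mammary carcinomas (4 and 4 arrays). Epithelial genes were lower in fibrosarcomas, as for the adhesion gene Epcam (-7.37 ± 0.12), Krt7 (-7.42 ± 0.18), the claudin gene Cldn3 (-5.96 ± 0.14) and the receptor gene Erbb3 (-6.03 ± 0.12). In the epithelial list of unirradiated tumours, 3 of 25 were higher, 22 lower and 0 did not pass, or 3 and 22 adjusted over the list alone. The median was -2.79 (camera adjusted p = 1.15e-14, adjusted p = 1.83e-06 with an estimated correlation). The milk casein gene Csn3 (-7.24 ± 0.15), Igfbp2 (-8.28 ± 0.17) and the aldolase gene Aldoc (-8.17 ± 0.15) were lower. The growth factor receptor gene Pdgfra (4.47 ± 0.21), the transcription factor gene Twist2 (3.83 ± 0.15), S100a4 (3.93 ± 0.16), Crabp1 (6.43 ± 0.23) and the granzyme gene Gzmf (6.84 ± 0.61) were higher. Mrc1 (4.08 ± 0.26) and Ccl2 (4.50 ± 0.18) were higher too. Iigp1 (-4.19 ± 0.27) and Ifit1 (-2.89 ± 0.21) were lower. Skeletal muscle genes had a median of 2.12. limma called 8689 of 12885 genes (5326 higher, 3363 lower), with 1656 and 1106 at least 2-fold apart, and 817 with 1 value per group.

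At day 5 after carbon ions, the squamous cell carcinomas scc7 and nrs1 were set against the other 4 tumours (4 and 8 arrays). The cornified envelope genes Sprr2f (5.11 ± 0.17, 0.19 to 10.10 across pairs of tumours) and Sprr1b (4.24 ± 0.12) were higher in squamous cell carcinomas. For epithelial genes in this comparison, 19 of 27 were higher, 4 lower and 4 did not pass, or 19 and 4 adjusted over the list alone. The median was 0.72 (camera adjusted p = 0.00135, adjusted p = 0.159 with an estimated correlation). The chemokine gene Ppbp (4.47 ± 0.20), the fatty acid elongase gene Elovl4 (4.34 ± 0.14) and the haem oxygenase gene Hmox1 (1.64 ± 0.12) were higher. Tgfbi (-1.87 ± 0.20), Ltbp1 (-2.60 ± 0.14), which binds latent TGF-beta, the endothelial gene Esm1 (-2.11 ± 0.21), Pax6 (-3.62 ± 0.12) and Rsad2 (-2.21 ± 0.25) were lower. Of TGF-beta pathway genes, 2 of 18 were higher, 10 lower and 6 did not pass, or 2 and 10 adjusted over the list alone. The median was -0.43 (camera adjusted p = 0.00705, adjusted p = 0.0394 with an estimated correlation), a call lost in the floor setting (adjusted p = 0.0676). Rplp0 was higher (1.16 ± 0.072), but not in the floor setting (0.148, adjusted p = 0.856). The muscle list had a median of 0.70. limma called 8709 genes (5137 higher, 3572 lower), and 0 with 1 value per group (2168 at an unadjusted p under 0.05). After quantile normalization 4133 were higher and 4039 lower. In a simpler model another pair of tumours set against the rest gave more genes than these (2591 against 2412). No unirradiated arrays of scc7 or nrs1 were used here, so these values mix tumour type and response.

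Unirradiated mmca and mca4 arrays of the carbon experiment were set against those of the gamma experiment (4 and 4 arrays). The carbon arrays had higher values of Mcm7 (2.23 ± 0.18), the DNA repair gene Xrcc5 (2.39 ± 0.16), the elongation factor gene Eef2 (2.30 ± 0.17), Fos (2.27 ± 0.21), the chaperones Hsph1 (2.09 ± 0.16) and Hspa1a (1.91 ± 0.32), and Rsad2 (1.84 ± 0.29). Tbr1 (-2.66 ± 0.22) and Gata5 (-2.48 ± 0.21) were lower on the carbon arrays, and skeletal muscle genes differed by a median of 0.50. limma called 7073 genes (3951 higher, 3122 lower), against 8229 and 659 after quantile normalization, which moved the median of all genes from 0.043 to 0.40. With 1 value per group limma called 0 (1353 at an unadjusted p under 0.05).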

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

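The tests of patterns and the counts over other splits were chosen after the results were seen. Tests of group differences flagged 3 results: the gamma day 1 response differed between fibrosarcomas and mammary carcinomas in 2812 genes, the carbon response of days 1 to 5 between mmca and mca4 in 74, and the day 1 response between carbon ions and gamma rays in 3290.

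The first pattern is the fall of 8 genes after gamma rays (Olfr143, Gata5, Acer2, Tbr1, Ttyh2, Calml3, Ret and Adcy10). In mmca and mca4, unirradiated carbon arrays lay below unirradiated gamma arrays by a median of -2.10 (-2.66 to -0.99), which fits gamma controls that stand apart from other arrays. The same carbon arrays differed from gamma arrays of 30 Gy by 0.17, against a median fall of 2.30 from the gamma controls, but these experiments differed in 7073 genes. Within the gamma experiment, unirradiated mmca arrays of day 9 lay above irradiated ones of days 9 and 19 by a median of 1.28, as a fall after irradiation would give. All 8 were higher at 50 Gy than in the mean of 30 and 70 Gy at day 1 (median 1.41), unlike a fall that grows with dose, yet below unirradiated arrays by a median of -0.874. So whether irradiation lowers these genes stays open. What sets those gamma arrays apart (animals, RNA or array run) stays open.

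The second pattern is the difference between 70 and 30 Gy at day 1. Over its 6488 genes, the 50 minus 30 Gy differences were regressed on the 70 minus 30 Gy differences of the other tumours. The slope was 0.923 in mmca and 1.18 in nfsa, where the dimmest values at 50 Gy lay near those at 70 Gy (0.0797 and 0.0798, 0.0769 and 0.0734), and 0.034 in the radiation-induced fibrosarcoma and -0.428 in mca4, where they lay nearer those at 30 Gy (0.112 and 0.118, 0.119 and 0.105). The gap of 1.25 between the mean slopes of these pairs fits array brightness or run. The mean slope of -0.197 in the latter pair is lower than a response graded by dose would give, but mca4 hardly shares the 70 Gy pattern (slope 0.322 at 70 Gy, against 1.07, 0.994 and 1.15 in the radiation-induced fibrosarcoma, mmca and nfsa). That leaves 1 tumour to test it, so a response to dose, graded or with a threshold, stays open.

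The third pattern is the rise of epithelial genes after carbon ions in mmca and mca4, with a median of 1.26 over the 17 that rose at day 5. Skin taken with the tumour could bring such genes. The 9 measured genes of a 12-gene skin list changed by a median of -0.0957 (highest 0.333), but just 2 of them exceeded 2 on any array (Flg 3.19, Lor 2.44) and 4 stayed below -0.5 on every array, so most could not have shown skin, which stays open. Scaling is argued against by the 17 epithelial genes' median rise of 1.41 after quantile normalization. No biological explanation was tested.

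Other splits were counted with a simpler model on the 8689 genes present on every array, moving arrays within tumours where a comparison spans several. The real split gave the highest count in 1 of 100 splits for the gamma day 1 mean (3173 genes, highest other 22), dose (4696, 995), gamma days 8 to 25 (4925, 1), the last carbon group against day 5 (2039, 136) and nfsa days (63, 0). Chance can be excluded there if the arrays of a group are separate animals. With 1 value per group, limma called 0 for the last carbon group and for nfsa days (1566 and 986 at an unadjusted p under 0.05).

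For types of tumour, whole tumours were moved, and the splits are too few for a share under 0.05. The real and highest other counts were 216 and 1143 for the response by tumour type (2 of 3 splits gave as many), 2793 and 445 for unirradiated tumour types (1 of 3) and 2412 and 2591 for squamous cell carcinomas (2 of 15). The 18 splits are too few as well in 6 comparisons, with counts of 1772 and 0 at carbon hour 6, 1449 and 24 at day 1, 4484 and 0 at day 3, 5740 and 0 at day 5, 6334 and 0 at day 20, and 2781 and 486 for unirradiated carbon against gamma arrays.

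Splits also decide nothing in 3 comparisons. For mmca against mca4 over carbon days 1 to 5 (1 gene, 7 of 100 splits gave as many, highest other 4406) and carbon against gamma (1256, 3 of 100, 1636), they exchanged irradiated and unirradiated arrays, bringing in the response itself. For the last 50 Gy days the simpler model called 0 genes in limma, which all 60 splits match (highest other 125).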

How the results depend on the processing

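Counts of called genes stayed within 1.5 times the main count, for all 25 comparisons, after quantile normalization, without the dim filter, with the other floor, without the trend and with the replicate block, and for the 4 comparisons tested with pooled mmca controls. 4 settings named at the start were chosen after seeing the data. The cause was not tested for any change below unless stated. The number of arrays per group, the missing dim values on gamma arrays and the floor limit what can be seen of weak signals.

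With 1 value per group, which leaves 1 to 11 residual degrees of freedom and so fewer calls by construction, counts were 1019 for the gamma day 1 mean, 4, 0, 56 and 53 for the radiation-induced fibrosarcoma, mmca, nfsa and mca4, 40 for dose, 0 for tumour type, 3528 for gamma days 8 to 25, 1910, 0, 0 and 4187 for its 4 tumours, 315, 142 and 4273 at carbon hour 6, day 1 and day 3 (6947 and 8482 at days 5 and 20), and 817 for unirradiated tumour types. limma called 0 for mmca against mca4, carbon against gamma, the last carbon group, nfsa days, the last 50 Gy days, squamous cell carcinomas and unirradiated carbon against gamma, with 168, 702, 1566, 986, 754, 2168 and 1353 genes at an unadjusted p under 0.05. This setting ended the call of 208 of 394 named genes and 17 of 262 lists.

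Testing every probe, which counts genes more than once by construction, gave 13801, 11387, 7661, 6544 and 9561 probes for the gamma day 1 mean, the radiation-induced fibrosarcoma, mmca, nfsa and mca4, 12087 for dose, 4258 for tumour type, 17074, 15693, 9614, 13351 and 14866 for gamma days 8 to 25 and its 4 tumours, 8664, 12644 and 15488 at carbon days 3, 5 and 20, 5884 for carbon against gamma, 9071 for the last carbon group, 4453 for nfsa days, 4451 for the last 50 Gy days, 14512 for unirradiated tumour types, 15212 for squamous cell carcinomas and 12641 for unirradiated carbon against gamma. Array weights gave 3501 at carbon hour 6, 3544 at carbon day 1, 1481 for mmca against mca4, 4944 for carbon against gamma and 4318 for nfsa days. A fit of only a comparison's own arrays gave 3377, 3590, 1711, 5055 and 1272 for these 5, and 18 for the last 50 Gy days. Missing values at the floor with quantile normalization gave 1650 for tumour type and 216 for mmca against mca4.

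With the replicate block (pairing check above), counts differed most for squamous cell carcinomas (7793 against 8709) and mmca against mca4 (85 against 74), and at carbon day 1 1125 genes passed.

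Leaving out each array gave 2270 to 4142 genes for gamma day 1 in mmca (lowest without replicate 2 of unirradiated day 1), 1681 to 3595 in nfsa (without replicate 2 of the unirradiated group), 3556 to 5430 for late mmca (without replicate 2 of unirradiated day 9), 721 to 910 at carbon hour 6 (without unirradiated mmca replicate 1), 570 to 660 at carbon day 1 (without unirradiated mca4 replicate 2), 12 to 64 for mmca against mca4 (without unirradiated mmca replicate 2) and 1217 to 3022 for the last 50 Gy days (lowest without mca4 day 41 replicate 2). Other arrays that moved a count by over 1.5 times were replicate 1 of unirradiated mmca at gamma day 1 (2549), all 8 arrays of carbon day 1, all 8 of hour 6 except unirradiated mmca replicate 2 and irradiated mca4 replicate 1, and for the last 50 Gy days scc7 day 23 replicate 2 (1259) and scc7 day 35 replicate 1 (1435). For mmca against mca4 these were unirradiated mca4 replicates 1 (17) and 2 (15), unirradiated mmca replicate 1 (37), and replicate 1 of irradiated mmca at day 1 (43) and day 3 (48). The other comparisons stayed within 1.5 times. A lone array left in a group is assumed to vary like the other groups. Of 5692 gene values, 5579 kept direction and call, 99 lost the call and 14 turned: Trp53inp1 ranged from -0.0452 to 0.0353 in the gamma day 1 mean and from -0.118 to 0.0904 at carbon hour 6, and Mdm2 from -0.0427 to 0.0802 in mmca at gamma day 1, none of them called.

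Some values turned sign. After quantile normalization and with missing values at the floor, Trp53inp1 gave 0.0877 and 0.0669 in the gamma day 1 mean (0.0883 at brightness-matched doses), 0.0275 and 0.0314 at carbon hour 6, and Mdm2 gave 0.00178 and 0.000962 at carbon day 20. With missing values at the floor, Uqcrb gave 1.06 between 70 and 30 Gy. There the oxidative phosphorylation list had a median of 0.00152 after quantile normalization and stayed below 0 with missing values at the floor (-0.00337), where camera ranked it as higher. That list's median for the last 50 Gy days was -0.0609 after quantile normalization and -0.0415 with missing values at the floor. Mdm2 gave -0.597 for gamma day 1 in mmca at brightness-matched doses, a called fall (adjusted p = 0.00538). Against the day 1 control, late mmca gave -0.0818 for Mdm2, 0.16 for the ribosomal list and 0.189 for the oxidative phosphorylation list.

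Quantile normalization left 381 of 394 named genes with direction and call and ended the call of 10, own arrays left 376 and ended 16, missing values at the floor left 364 and ended 26, and array weights, block, no filter, no trend and the other floor left 391, 391, 393, 393 and 394. Of 262 called list shifts, 33 stayed called with an estimated correlation, 223 after quantile normalization, 214 with missing values at the floor, 254 from own arrays, 255 with the block and 245 with 1 value per group.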

Other observations

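Squamous cell carcinomas after gamma rays lack unirradiated arrays here, so log2 intensities are given with the SD between arrays. Krt14, a basal keratin, was at 8.46 ± 0.112 in nrs1 at day 8 after 30 Gy (n = 3) and -2.11 ± 0.068 in scc7 at the same day and dose (n = 2). After carbon ions at day 5 it was at 8.73 ± 0.0536 in nrs1 and -1.21 ± 0.205 in scc7 (n = 2 each), so the 2 squamous tumours lie far apart in this gene. The T cell gene Cd3g was at 0.94 ± 0.467 in nrs1 and 4.18 ± 0.597 in scc7 at day 8 after 30 Gy of gamma rays. At day 5 after carbon ions Cd3g was at 2.74 ± 0.122 in nrs1 and 6.39 ± 0.128 in scc7. Cdkn1a was at 6.12 ± 0.0451 in nrs1 at day 8 after 30 Gy and 5.91 ± 0.19 at day 15 after 50 Gy (n = 3 each), and in scc7 at 5.67 ± 0.0116 at day 8 after 30 Gy and 5.08 ± 0.104 at day 35 after 50 Gy (n = 2 each). Differences between these groups were not tested.

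In mmca, unirradiated gamma arrays of day 9 and day 1 differed in 2743 genes of 12909 (884 higher and 1859 lower at day 9), of which 110 were higher and 31 lower at least 2-fold. The SD of the skeletal muscle list mean within groups reached 1.51 log2 in 18 later gamma groups, 0.154 in 16 day 1 gamma groups and 0.126 in 20 carbon groups.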
